A study of Rattus norvegicus with 6 samples.

How the data were processed

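Total RNA of rat nucleus pulposus was made into small RNA libraries selected at about 22 nt and sequenced for 50 cycles on an Illumina NovaSeq, per the labels' protocols. The 6 libraries, 3 IDD and 3 Sham, were grouped by their titles and treatment labels. The deposited counts are raw tag counts per mature sequence, per the file headers. The submitters' processing notes name cutadapt 1.9.3, Novoalign 3.02.12 and the build Rnor_6.0, without saying which step used which, and the program that called miRNAs is not given in the sources used here. A blank cell stands for a sequence that was not listed in that library. It was set to 0, although the lowest listed value of 2 means that 1 is also possible. The second table holds a normalized tag count per library that the authors rounded to whole numbers, treated here as a score: its values equal the deposited counts times 1 factor per library, whose basis is not given in the sources used here. It was used only as an alternative. No genome positions are given, because the provisional names carry a chromosome without coordinates and the gene table at hand is on another build.

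The 491 rows repeat some mature sequences, with identical counts on each repeat, and were reduced to 442 distinct sequences. Sequences were filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3, minimum count 10), which left 131, scaled with TMM, and tested with the robust quasi-likelihood test of IDD against Sham, two-sided, at a Benjamini-Hochberg adjusted p below 0.05. The biological coefficient of variation was 10.2%. CPM are deposited counts over the TMM-scaled library totals. Library totals of 169783 to 253807 tags make 3 counts worth 11.6 to 17.0 CPM, and this floor covers counting error only, since PCR copies are not independent molecules. Folds against a group that was blank throughout are lower bounds from a floor of 3 counts per library, and hold only if a blank stands for at most 3 counts. Intervals on ratios of summed counts are exact binomial (Clopper-Pearson) at 95% and cover counting error only. Lists with at least 3 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation, and with fry. Shares were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. Arms of one precursor were set side by side by correlation with 100000 permutations, and the ratio of arms was tested with limma.

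The design, the 25 miRNA lists, the alternatives and the rule for named miRNAs were fixed before the data were examined. The rule took, among sequences past the threshold whose 3 IDD values all lay on one side of the 3 Sham values, the 12 with the largest absolute log2 fold change in each direction (if fewer than 6 passed in a direction, those of lowest unadjusted p filled it to 6, which was not needed). It added the 10 of highest mean CPM and, of each list, up to 4 members past the threshold by lowest adjusted p or, where none passed, the 2 of highest mean CPM. Further members of lists, both arms of precursors and sequences listed in 1 group alone are named where a count is described and were chosen after their values were seen. List members were matched by name, which left miR-1b out of the muscle list, and miR-450b was not among the names of the X-linked list.

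The numbers 1 to 3 are shared by the groups. Libraries with the same number deviated together from their group means, with correlations of 0.111, 0.112 and 0.204, each over 0.1, so the numbers were taken to pair the libraries. The pairing comes from these values and not from a label, and IDD 2 with Sham 1, of different numbers, had a correlation of 0.109, about that of the lower same-numbered pairs. The fit with the number as a block was an alternative. The others were other scalings, other filters, DESeq2 1.42.0, limma-voom, the likelihood ratio test, limma on log2 of the authors' normalized values plus 1, other thresholds and each library left out in turn. The fits were tested on simulated data before use. With 131 sequences simulated for IDD versus Sham, 20 times, with 20 changed per fold size, 89.8% of 2-fold and 62.5% of 1.5-fold changes were recovered, 3.15% of calls were false and every recovered change had the right sign. The simulations planted fewer changes than were called here, none above 2-fold, and drew counts no more even than counting noise. Their rates may therefore not hold for these libraries. Plots were drawn with matplotlib 3.10.9.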

Results

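Small RNA libraries were compared between the nucleus pulposus, the gel-like core of the intervertebral disc, of rats whose discs had been compressed for 4 weeks to induce degeneration (IDD, 3 libraries) and that of sham rats, labelled as having K-wires for 4 weeks (Sham, 3 libraries). The question set by the study's design was which miRNAs respond to mechanical load in degenerating discs. After rows that repeat the same mature sequence were merged, the tag counts summed to 246422, 189802 and 214761 in IDD 1, 2 and 3. In Sham 1, 2 and 3 the tag counts summed to 253807, 251730 and 169783. Total depth therefore did not separate the groups (217000 ± 28380 against 225100 ± 47920, SD, n = 3 each, exact two-sided permutation test, p = 0.8). The table held 442 distinct sequences, 204 under an established miRNA name and 238 under a provisional name built from a chromosome. Depth over the established miRNAs alone did separate the groups (175700 ± 28500 tags in IDD against 118900 ± 20920 in Sham, SD, n = 3 each, exact two-sided permutation test, p = 0.1). The lowest IDD library held 147728 such tags and the highest Sham library 135609. The deposited table leaves cells blank, and its lowest listed count was 2. An IDD library listed 258 to 273 sequences and a Sham library 305 to 322. Within each group, the log2 of scaled tag counts (CPM) of replicates correlated at a Pearson r of 0.9931 to 0.9955 across sequences, which are not independent replicates, and every pair of replicates differed by more than counting noise (chi-square per degree of freedom 5.245 to 25.27). Nothing in the labels says whether each library came from a separate animal, so p-values measure the spread between these samples.

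The libraries were dominated by a few sequences. miR-1b, whose sequence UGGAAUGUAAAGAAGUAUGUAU is that of the muscle miRNA known in mouse and human as miR-1, took 40.5% ± 2.28 of tags in IDD and 21.5% ± 1.27 in Sham (SD, n = 3). miR-140-3p, made from an intron of the cartilage-expressed gene Wwp2, took 11.8% ± 0.257 and 8.59% ± 1.26 of all tags. Over the tags of established miRNAs alone, miR-1b took 50.2% ± 2.10 in IDD and 40.4% ± 0.262 in Sham (exact two-sided permutation test, p = 0.1), whereas miR-140-3p took 14.7% ± 0.264 and 16.1% ± 1.44 (p = 0.3), so its direction turned with the denominator. The provisionally named tags together went the other way, from 46.8% ± 3.41 of tags in Sham to 19.2% ± 2.67 in IDD, and nearly all of this was carried by tags that end in CCA. Tags with that end held 44.2% ± 3.66 in Sham and 17.1% ± 2.63 in IDD, of which the 18-nt tag AUCUCGGUGGAACCUCCA alone made up 36.9% ± 3.0 and 14.1% ± 2.23, and the other provisionally named tags held 2.65% ± 0.278 and 2.14% ± 0.139. For each of these shares of all tags the groups did not overlap, at the smallest p that 3 against 3 libraries allow (0.1, exact two-sided permutation test). The 10 most abundant sequences together held 86.2% ± 0.713 in IDD and 86.6% ± 0.838 in Sham (exact two-sided permutation test, p = 0.5).

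**Figure D1:**
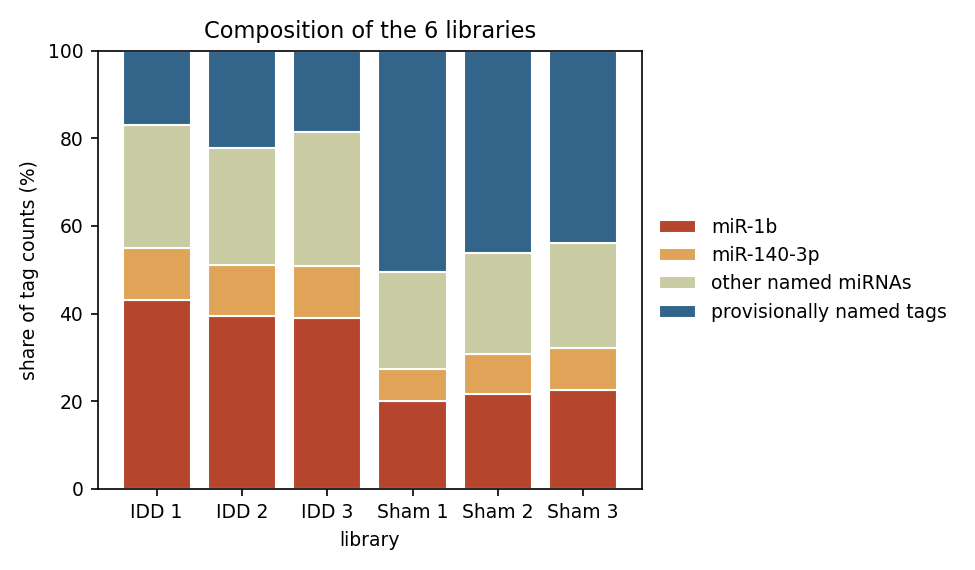
Stacked bars give the share of tag counts, in percent, of miR-1b, miR-140-3p, the other named miRNAs and the provisionally named tags in each of the 6 libraries. The provisionally named tags take 43.8% to 50.5% of each Sham library and 16.9% to 22.2% of each IDD library.

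Compression was accompanied by changes in 78 of 131 tested sequences, 38 higher and 40 lower in IDD. Among the largest rises were miR-125a-5p (3.44-fold), miR-206-3p (3.28-fold), miR-7a-5p (2.87-fold), miR-342-3p (2.53-fold), which is enriched in leukocytes, miR-21-5p (2.34-fold), which rises in fibrosis, and miR-29a-3p (2.26-fold), a family that targets collagen mRNAs. Among the largest falls were miR-1843a-3p (6.44-fold lower), miR-10a-5p (3.72-fold lower), encoded in a Hox cluster, miR-16-5p (3.64-fold lower), linked to cell cycle arrest, and miR-672-5p (3.43-fold lower). miR-6321 was listed in all 3 IDD libraries and blank in all Sham libraries, and miR-200a-3p, an epithelium-enriched miRNA, was listed in all 3 Sham libraries and blank in all IDD libraries. Of the 78 calls, 62 were established miRNAs (36 higher, 26 lower) and 16 were provisionally named tags (2 higher, 14 lower).

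The rises were as follows in CPM with TMM scaling (mean ± SD, n = 3 per group). Each has a log2 fold change, a standard error (SE) and the Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test. The SE is not given by edgeR. It was derived here as the absolute log2 fold change over the square root of the test's F statistic. miR-21-5p rose from 2339 ± 219 to 5467 ± 481 CPM (log2 1.23, SE 0.12, adjusted p = 4.13e-06). miR-29a-3p rose from 604 ± 72.7 to 1370 ± 85.6 CPM (1.17, SE 0.12, adjusted p = 7.47e-06). miR-7a-5p rose from 69.7 ± 6.80 to 203 ± 6.94 CPM (1.52, SE 0.18, adjusted p = 1.68e-05). miR-206-3p rose from 51.6 ± 14.02 to 169 ± 38.6 CPM (1.71, SE 0.26, adjusted p = 7.82e-05). miR-125a-5p rose from 16.3 ± 6.61 to 55.7 ± 12.5 CPM (1.78, SE 0.30, adjusted p = 0.000307). The other 6 named risers with a finite fold lay between 1.88-fold (miR-1839-5p) and 2.53-fold (miR-342-3p), namely those 2 and miR-340-5p, miR-455-3p, miR-490-5p and miR-378a-5p. The call of miR-490-5p was lost under 2 settings (adjusted p up to 0.0878). miR-6321 had 46, 13 and 20 counts in IDD 1, 2 and 3, at least 7.51-fold above a floor of 3 counts per Sham library (adjusted p = 0.0145), a call lost under 2 settings (adjusted p up to 0.0640). Of the most abundant miRNAs, miR-1b rose by 0.74 on the log2 scale (SE 0.11, adjusted p = 5.19e-05), miR-26a-5p by 0.70 (SE 0.11) and miR-140-3p by 0.29 (SE 0.10, adjusted p = 0.0230).

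The falls included the most abundant tag of the Sham libraries, AUCUCGGUGGAACCUCCA, which fell from 398416 ± 76697 to 132731 ± 24312 CPM (log2 −1.59, SE 0.16, adjusted p = 1.14e-05). A second 18-nt tag, AUCUCGGUGGGACCUCCA, fell from 70574 ± 13833 to 27200 ± 4303 CPM (log2 −1.38, SE 0.15). A further 3 provisionally named tags are among the 12 largest falls, CGUGACUGUACCUGGUAU (log2 −2.48, SE 0.25), AUCUCGCUGGGGCCUCCA (−2.29, SE 0.24) and UAGGGAACGUGAGCUGG (−1.89, SE 0.13). miR-10a-5p fell from 12783 ± 2510 to 3445 ± 474 CPM (log2 −1.89, SE 0.15, adjusted p = 2.04e-06). miR-1843a-3p fell from 106 ± 27.4 to 16.3 ± 4.45 CPM (−2.69, SE 0.30, adjusted p = 1.14e-05), and miR-16-5p fell from 75.2 ± 4.28 to 19.7 ± 6.44 CPM (−1.86, SE 0.24, adjusted p = 3.05e-05). miR-672-5p (−1.78, SE 0.23), miR-30a-3p (−1.40, SE 0.17) and miR-361-3p (−1.35, SE 0.19) also fell. miR-200a-3p had 27, 33 and 64 counts in Sham 1, 2 and 3, at least 15.9-fold above a floor of 3 counts per IDD library (adjusted p = 0.0214), a bound of 10.1-fold without Sham 3. Of the most abundant miRNAs, miR-101a-3p (−0.48, SE 0.15) and miR-100-5p (−0.42, SE 0.11) fell, calls lost under 4 and 2 settings (adjusted p up to 0.116 and 0.182).

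Some of these folds rest on few tags. miR-1843a-3p had 11 counts over the 3 IDD libraries against 66 in Sham, a ratio of summed counts of 6.63 with a 95% exact counting interval of 3.48 to 13.9. miR-125a-5p had 39 counts in IDD against 10 in Sham (3.53, interval 1.73 to 7.93), and miR-16-5p 14 against 47 (3.71, interval 2.01 to 7.30). At group means of 3 to 12 counts replicates varied less than counting noise (dispersion index 0.452). For these 3 miRNAs the counting intervals are wider than the SE printed above would give. The SE of low counts can therefore be too small, and their adjusted p may be too low.

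The 3 IDD values lay on one side of the 3 Sham values for 76 of the 78 calls and for 87 of the 131 tested sequences, where chance gives 10%. A fold of at least 2 was reached by 10 of the 38 rises and 24 of the 40 falls. The first principal component held 88.3% of the variance and separated the groups. The split of 38 higher and 40 lower depends on the scaling, being 52 and 29 with library size alone, 60 and 30 on the authors' normalized values and 29 and 44 when scaled on established miRNAs alone, which move the median log2 fold change by 0.19, 0.23 and −0.16. The calls of miR-140-3p (adjusted p from 0.000430 to 0.350 over its alternatives), miR-378a-5p (0.00825 to 0.212) and miR-200a-3p (up to 0.128) were each lost under 9 or more settings, and without Sham 2 the count of rises was 24 and that of falls 34.

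**Figure D2:**
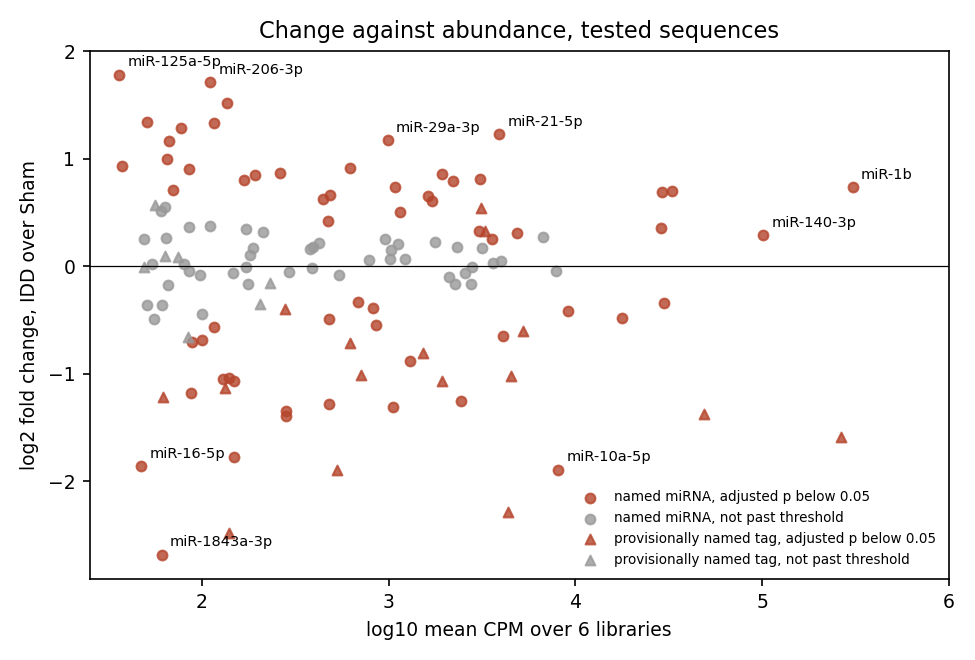
Each point is a tested sequence, with the log10 mean CPM over the 6 libraries on the x axis and the log2 fold change of IDD over Sham on the y axis. Triangles are provisionally named tags and colour marks an adjusted p below 0.05, and miR-6321 and miR-200a-3p, blank in a whole group, are left out. Falls of over 1 log2 unit include the abundant tags at the right, and miR-1b at the far right rose by 0.74.

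**Figure D3:**
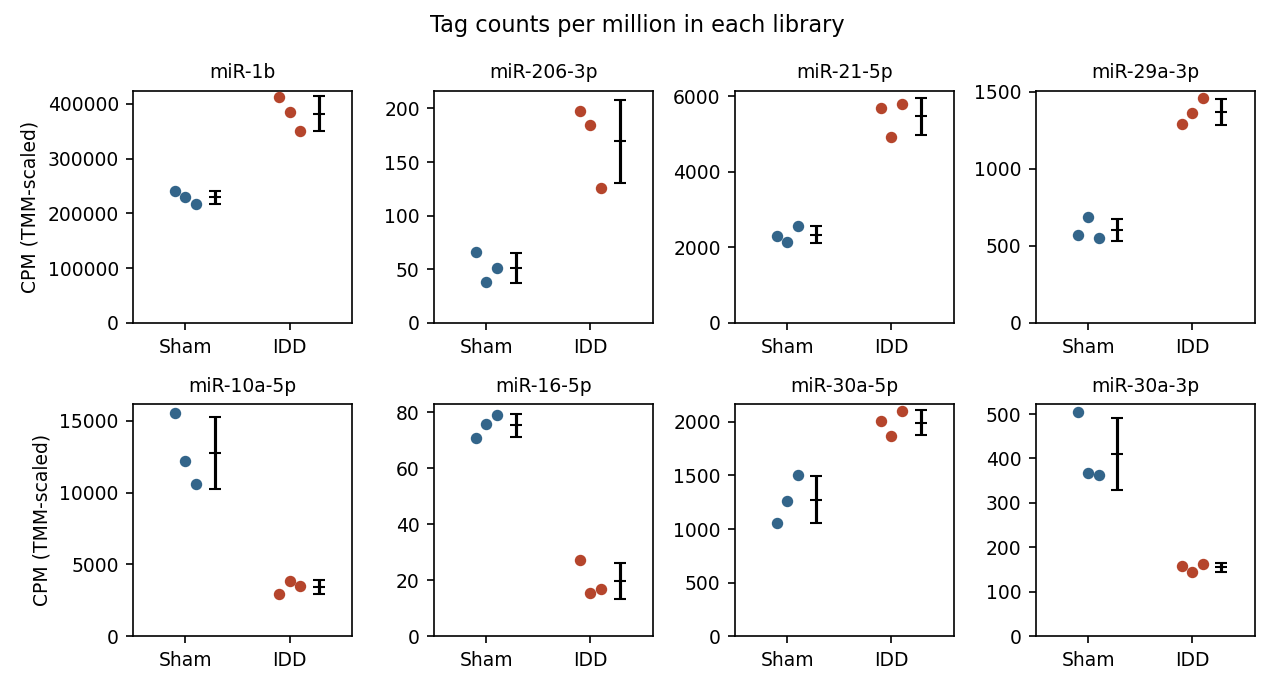
Points give CPM with TMM scaling in each of the 3 Sham and 3 IDD libraries for 8 miRNAs, and the bar beside each group gives its mean and SD. The 3 IDD values lie above all Sham values for miR-1b, miR-206-3p, miR-21-5p, miR-29a-3p and miR-30a-5p and below them for miR-10a-5p, miR-16-5p and miR-30a-3p.

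The second question was whether groups of related miRNAs moved together. Among cartilage miRNAs, miR-455-3p (log2 1.16, SE 0.30) and miR-140-3p (0.29, SE 0.10) rose, and miR-455-5p (−0.04, adjusted p = 0.916) did not pass. The call of miR-455-3p was lost under 2 settings (adjusted p up to 0.0749). miR-140-5p did not pass without the replicate block (0.27, adjusted p = 0.0681) and passed with it (0.27, adjusted p = 0.0179). Among muscle miRNAs, miR-206-3p (1.71) and miR-1-3p (0.74, SE 0.18) rose, and miR-133a-3p (0.55, adjusted p = 0.124) and miR-499-5p (−0.08, adjusted p = 0.821) did not, and the call of miR-1-3p was lost under 1 setting (adjusted p = 0.0615). Among fibroblast and mesenchyme miRNAs, miR-21-5p (1.23) and miR-199a-3p (0.33, SE 0.11) rose and miR-199a-5p (−0.08, adjusted p = 0.684) did not. None of the 10 lists with at least 3 tested members stood apart from the other sequences with camera (lowest adjusted p = 0.861, and adjusted p = 0.978 with an estimated correlation), and 0 had an unadjusted p below 0.05. For the miR-30 family, the miR-15 and miR-16 family and the load or flow list the median log2 fold change was above 0 and the mean below it, with camera's direction down for the first 2 and up for the load or flow list. fry, which asks only whether a list's own members moved on balance one way, passed 5 of the 10, namely cartilage (adjusted p = 0.0316), skeletal muscle (0.0124), fibroblast and mesenchyme (0.0102), load or flow responsive (0.0102) and studied before in disc degeneration (0.0393). Some of these lists share members. miR-21-5p is in the fibroblast, load or flow and disc degeneration lists, and both miR-140 arms are in the cartilage and disc degeneration lists. The load or flow list had a median log2 fold change of 0.18 and a mean of −0.029, so its members are not shown to have moved together.

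The share of tags held by muscle miRNAs was 0.182% ± 0.0305 in IDD and 0.0964% ± 0.00331 in Sham (exact two-sided permutation test, p = 0.1), or 0.225% ± 0.0336 and 0.182% ± 0.0181 of the tags of established miRNAs (p = 0.2), without miR-1b, the main muscle sequence, which the list's name rule missed. With miR-1b added after the values were seen, the list held 5 tested members with a median log2 fold change of 0.74 and camera gave an adjusted p of 0.613. Markers of other cell types moved both ways. miR-486, the only tested member of the red blood cell list, fell (log2 −0.39, SE 0.11, adjusted p = 0.00650), a call lost under 3 settings (adjusted p up to 0.272). miR-342-3p of the leukocyte list rose (1.34, SE 0.22, adjusted p = 0.000781) while miR-146b-5p of that list did not (−0.01, adjusted p = 0.975). The only listed epithelial miRNA was miR-200a-3p. miR-143-3p of smooth muscle (−0.45, adjusted p = 0.112), miR-128-3p of the neural list (0.35, adjusted p = 0.101) and the liver miRNA miR-122-5p (−0.04, adjusted p = 0.741) did not pass, and miR-122-5p nevertheless held 0.826% ± 0.0320 of all tags in IDD and 0.754% ± 0.0979 in Sham, or 1.02% ± 0.0493 and 1.42% ± 0.102 of the tags of established miRNAs. miR-122 had been fixed beforehand as a negative control not expected in disc. It was present in every library, so this control failed, and the source of its tags was not tested. No endothelial miRNA was abundant enough to test, and the list held 0.00278% ± 0.000430 of tags in IDD and 0.00375% ± 0.000501 in Sham, or 0.00344% ± 0.000540 and 0.00707% ± 0.00106 of the tags of established miRNAs.

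Members and arms of the miRNA families moved in both directions. In the let-7 and miR-98 family, let-7g-5p (log2 0.69, SE 0.10) and let-7f-5p (0.36, SE 0.11) rose, let-7i-5p (−0.34, SE 0.11), let-7e-5p (−0.49, SE 0.16) and miR-98-5p (−0.69, SE 0.26) fell and 5 of the 10 tested members did not pass. The calls of miR-98-5p, let-7i-5p, let-7f-5p and let-7e-5p were lost under 7, 5, 5 and 4 settings (adjusted p up to 0.260, 0.422, 0.184 and 0.134), and that of miR-199a-3p under 6 (up to 0.233). In the miR-30 family, miR-30d-5p (0.86, SE 0.11), miR-30b-5p (0.66, SE 0.12) and miR-30a-5p (0.65, SE 0.13) rose, whereas among the 3p arms, which do not carry the family's seed, miR-30a-3p, miR-30e-3p (−1.28, SE 0.23) and miR-30c-2-3p (−1.18, SE 0.25) fell. In the miR-15 and miR-16 family, miR-195-5p rose (0.80, SE 0.20) and miR-16-5p and miR-322-5p (−1.04, SE 0.17) fell. miR-29a-3p was the only tested member of the miR-29 family. None of the 4 tested members of the miR-17-92 and paralogous clusters passed, among them miR-25-3p (−0.06, adjusted p = 0.682) and miR-106b-3p (0.02, adjusted p = 0.975), whose signs change with the scaling. miR-34c-5p (0.32, adjusted p = 0.122) did not pass, and no member of the miR-181 family or the miR-183 cluster was abundant enough to test. Of the tested named miRNAs, 24 of 108 differ from another listed sequence by 1 base, contain one or lie inside one, including let-7f-5p, miR-1-3p and miR-30a-5p, so their counts are uncertain where the authors' counting could split them.

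Genomic clusters and response lists had few tested members. Over all tested sequences 78 of 131 passed, so the number of calls does not by itself set these lists apart. Of the Hox cluster miRNAs, miR-10a-5p fell and miR-10b-5p did not pass (−0.50, adjusted p = 0.193). In the imprinted Dlk1-Dio3 cluster, miR-379-5p fell (−1.07, SE 0.18) and miR-127-3p did not pass (0.51, adjusted p = 0.163). In the list for the X-linked miR-322 and miR-503 cluster, miR-322-5p fell and 3 of the 4 tested members did not pass. That list holds miR-450a but not miR-450b, and miR-450b-5p, looked at after its values were seen, fell (−0.55, SE 0.13, adjusted p = 0.0022). The hypoxia-responsive miR-210-3p fell (−0.33, SE 0.12, adjusted p = 0.0339), a call lost under 6 settings (adjusted p up to 0.506). Of the NF-kB and inflammation list, miR-21-5p rose and miR-146b-5p did not pass. Of 5 tested miRNAs reported elsewhere to respond to load or flow, miR-21-5p and miR-103-3p (0.79, SE 0.11) rose and miR-10a-5p fell. Of 8 studied before in disc degeneration, miR-21-5p and miR-140-3p rose, miR-210-3p and miR-98-5p fell and 4 did not pass. In each of the 25 lists, the number of calls adjusted over the list alone was the same as over all tested sequences.

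The shares of tags held by the 25 lists did not overlap between the groups for 16 of them. Fibroblast and mesenchyme miRNAs held 1.00% ± 0.0699 of all tags in IDD and 0.523% ± 0.0335 in Sham, or 1.24% ± 0.0644 and 0.983% ± 0.00935 of the tags of established miRNAs. The let-7 and miR-98 family held 11.3% ± 0.448 and 8.64% ± 0.195 of all tags, but 13.9% ± 0.0968 and 16.3% ± 0.770 of the tags of established miRNAs, where its direction turned. The Hox cluster held 0.378% ± 0.0513 and 1.20% ± 0.104 of all tags, or 0.470% ± 0.0762 and 2.27% ± 0.348 of the tags of established miRNAs. Each of these 3 differences over all tags had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allow, and shares of all tags also move with the provisionally named tags, which fell from 46.8% to 19.2%.

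The third question was whether both arms of a hairpin changed alike, since they are cut from one precursor. By the ratio of the arms they did not for 8 of 16 precursors, some of them with few tags in 1 arm, and for the others no difference was shown. Of 16 precursors with both arms tested, both arms passed in the same direction for miR-423 (−0.70 and −1.05 for 5p and 3p) and miR-490 (0.99 and 0.85), and in opposite directions for miR-30a (0.65 and −1.40) and miR-99b (−0.65 and 0.71). One arm alone passed for 8 precursors, among them miR-140, both of whose arms rose with the replicate block, and miR-1843a, whose 5p arm was at 0.37 (adjusted p = 0.169) and whose 3p arm fell by 2.69. A pass in a single arm does not by itself show that the arms differ. The ratio of the arms itself differed between the groups for 8 of 16 precursors (limma, Benjamini-Hochberg adjusted), by 3.07 on the log2 scale for miR-1843a (adjusted p = 3.45e-09) and 2.05 for miR-30a (adjusted p = 1.14e-06). This test used the log ratio of each library without weighting by counts, so counting error is not covered where an arm had few tags. For miR-378a, one of the 8 (adjusted p = 0.0113), the 5p arm had only 34 counts in IDD and 16 in Sham (95% counting interval of their ratio 1.03 to 3.73). Across the 16 precursors, which are not independent replicates, the log2 fold changes of the arms had a Pearson r of −0.026 (permutation p = 0.925) and a Spearman rho of 0.021 (permutation p = 0.943).

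**Figure D4:**
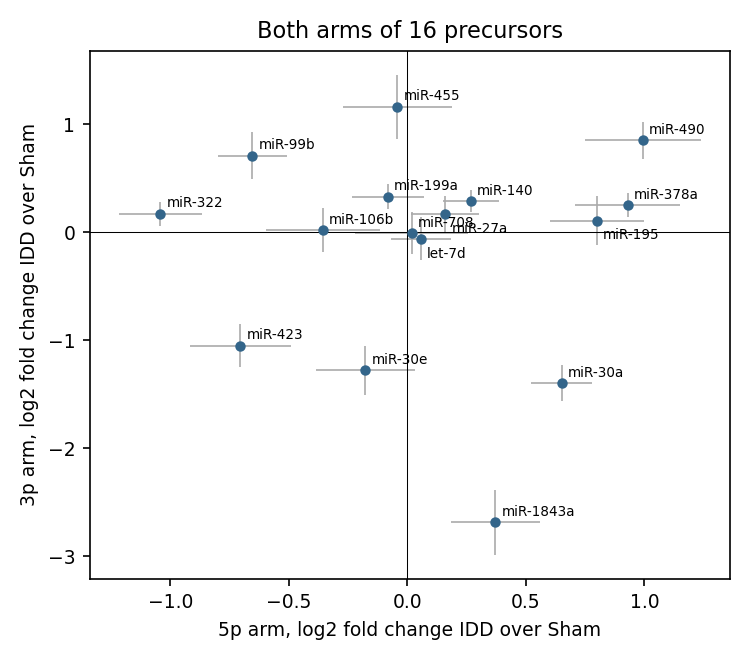
Each point is a precursor, with the log2 fold change of IDD over Sham of its 5p arm on the x axis and of its 3p arm on the y axis, and bars give 1 standard error. miR-30a and miR-1843a lie at the lower right, with a higher 5p value and a lower 3p arm, and miR-99b lies at the upper left.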

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

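All tests in this part were chosen after the results had been seen, except the count of splits. Outside the tested sequences, 66 that were too low to test were listed in all 3 IDD libraries and blank in all 3 Sham libraries. The opposite was more frequent, with 116 untested sequences listed in all Sham and no IDD libraries, and since a blank need not be 0 and the counts are low, a difference from the controls is not shown. Of the 66, 8 are established miRNAs and 58 provisionally named tags, and the highest count among them was 10.

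The real split of the 6 libraries gave 78 changed sequences and was 1 of 10 splits with as many, the highest other split having 0, also among the 4 splits that part all 3 same-numbered pairs. The other 6 splits part only 1 such pair. Every split but the real one puts IDD and Sham libraries on both sides. A difference between IDD and Sham then adds to the spread within each side, so few calls are likely there and the 0 is not a null rate. For lists tested with camera, 10 of 10 splits gave as many as the real 0, the highest other being 0. With 10 splits the share cannot fall under 0.1, which is too few for a share under 0.05.

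The first pattern is the fall of the provisionally named tags, where 13 of 17 tested tags of 17 to 18 nt fell and 0 rose (median log2 fold change −1.02), against 1 of 6 lower and 2 higher among those of 19 to 24 nt (median 0.09), where both higher tags lie inside miR-24-3p or miR-199a-3p and moved with them (0.54 against 0.50 and 0.33 against 0.33). An 18-nt tag inside miR-378a-3p had the opposite sign to it (−0.35, SE 0.17, against 0.25, SE 0.11), though neither passed the threshold. A loss that is the same for every tag of 17 to 18 nt, as size selection might give, is argued against by the spread of their log2 fold changes from −2.48 to 0.57 (Cochran's Q, a chi-square test that takes edgeR's standard errors as known, p = 6.53e-44), and a scaling set by the abundant tags is argued against because at least 13 of the 14 lower tags stayed past the threshold under 5 other scalings. The 3' ends of tRNAs with the added CCA cannot, by definition, account for the tested tags of 17 to 20 nt without that end, of which 11 of 17 also fell. For those that end in CCA, which held 44.2% of the 46.8% of tags in Sham and 17.1% of the 19.2% in IDD and so nearly all of the fall by share, this stays open: with near-identical tags counted once, 9 of 178 clusters end in CCA against 2.78 by chance (exact binomial p = 0.00211), but the 4 tested CCA tags fell in 1 cluster and no tRNA sequences were used here. Clusters were joined at an edit distance of up to 3, which can merge tags of different RNAs. A length-dependent loss that also varies with the sequence, RNA breakdown that differed between the groups and an effect of compression stay open, since no RNA quality values were used here. Which RNAs the provisionally named tags come from was not determined, as no tRNA or rRNA sequences were at hand. A provisional name does not show that a tag is a miRNA.

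The second pattern is that low counts vary little between replicates. Among sequences listed in all libraries of a group with a mean of 3 to 12 counts, the dispersion index was 0.452, where independent counting with values under 2 left blank gave 0.747 on average and at lowest 0.578 in 1000 draws. A rule that leaves values under 2 blank in a whole group is argued against as the source of this evenness by the index of 0.602 at a mean of 6 to 12, where draws gave 0.976 on average and 0.646 at lowest. Other listing rules were not drawn. Listing by whole group was frequent, with 117 sequences in all Sham and no IDD libraries and 67 the reverse. By comparison, 54 were listed in only part of Sham and 38 in only part of IDD. From 12 to 50 counts the index was 1.20. What made the low counts so even stays open, and no biological explanation was tested.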

How the results depend on the processing

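The alternatives called annotated scaling, annotated miRNAs only, all table rows, likelihood ratio test, without sequences blank in a whole group, annotated tags in the denominator and the muscle list with miR-1b were chosen after seeing the data. Against 78 calls, the other scalings, tests and tables gave 68 to 90, established miRNAs alone 56 of 107 tested, and an adjusted p below 0.1 gave 83. With no filter 285 changed (117 higher, 168 lower), because 442 sequences were then tested, and with at least 50 counts in 3 libraries 50 changed (24 and 26), because 74 were tested. With a 2-fold minimum 34 changed (10 and 24), the same counts as at an unadjusted p below 0.05 and 2-fold. On the deposited normalized values 60 were higher and the median log2 fold change moved by 0.231, near the 52 and 0.192 with library size only. Those values were also tested with limma, and the effects of scaling and of the test were not told apart. Leaving out each library gave 58 to 77 changed, 24 to 36 higher and 34 to 42 lower, and kept 58 (without Sham 2) to 70 of the 78 calls with no change of sign. The replicate block gave 80 calls, the 78 and 2 more (miR-140-5p and a provisionally named tag), lost none and called no list. fry passed 5 lists where camera passed 0, which compares a list with the other sequences as fry does not.

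The median log2 fold change moved by 0.192 with library size only, 0.231 on the deposited normalized values, −0.162 with annotated scaling, −0.132 with annotated miRNAs only and −0.111 without Sham 3. Over the named miRNAs and settings, 989 values kept their direction and side of the threshold, 78 no longer passed, 7 newly passed and 17 changed sign, all in miRNAs that did not pass, for which the cause was not tested. miR-122-5p turned to 0.131 with library size only, 0.0204 with no filter and 0.188 on the deposited normalized values. miR-25-3p turned to 0.124, 0.00525 and 0.170 in these, and ranged from −0.178 to 0.0375 over the libraries left out. miR-106b-3p turned to −0.0216 with DESeq2 size factors, −0.00182 without the 10 most abundant miRNAs, −0.0150 with DESeq2, −0.142 with annotated scaling, −0.112 with annotated miRNAs only and −0.0141 without sequences blank in a whole group, and ranged from −0.137 to 0.158 over the libraries left out. With a library left out, list medians that changed sign ranged from −0.109 to 0.0839 (let-7 and miR-98 family), −0.0927 to 0.140 (miR-30 family), −0.117 to 0.230 (miR-15 and miR-16 family), −0.158 to 0.0976 (miR-17-92 and paralogous clusters) and −0.162 to 0.0270 (X-linked miR-322 and miR-503 cluster), none of them past the threshold. The rho of the arms turned to −1 with at least 50 counts in 3 libraries, where only 3 precursors were left. With annotated tags in the denominator, the difference in share, IDD minus Sham, turned to −1.43 percentage points for miR-140-3p (3.25 over all tags), −2.34 for the let-7 and miR-98 family (2.62) and −0.391 for liver (0.0715), because the provisionally named tags leave the total. Depth limits the low sequences, since 311 of 442 were not tested.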

Other observations

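All tests in this part were chosen after the results had been seen. Below the level that could be tested, several X-linked miRNAs known from testis were listed mainly in Sham. miR-881-3p had 16, 7 and 7 counts, miR-741-3p 14, 8 and 7, miR-743a-3p 12, 7 and 5 and miR-471-5p 4, 3 and 3 in Sham 1, 2 and 3, and each was blank in all IDD libraries. miR-743b-3p had 16, 7 and 7 counts in Sham and 2 in IDD 2 alone. These miRNAs were chosen after their values were seen, out of 117 sequences listed in every Sham library and no IDD library, and no enrichment was tested.

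In the other direction, miR-214-3p, which shares a transcript with miR-199a, had 6, 9 and 5 counts in IDD 1, 2 and 3, miR-28-5p had 8, 7 and 10 and miR-125b-2-3p 6, 7 and 10, and each was blank in all Sham libraries. miR-221-3p had 19, 5 and 9 counts in IDD and 4 in Sham 1 alone. In all, 67 sequences were listed in every IDD library and no Sham library.

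The third pattern is the rise of the miR-1 sequences. A uniform rise of skeletal muscle RNA is argued against, since miR-1b, miR-1-3p, miR-206-3p, miR-133a-3p and miR-499-5p did not rise alike (Cochran's Q, a chi-square test that takes edgeR's standard errors as known, p = 1.59e-05, and 0.00157 for the first 3 of them). miR-1-3p, which differs from miR-1b by 1 base, may be misread miR-1b tags: it had 0.354 ± 0.0582 counts per 100 of miR-1b in IDD and 0.353 ± 0.0423 in Sham, a difference of 0.00891 SD, though shared production of both would give the same. miR-133a-3p, also a muscle miRNA, had only 0.0132 to 0.0287 counts per 100 of miR-1b in the IDD libraries and 0.0196 to 0.0239 in the Sham libraries. Why miR-1b so exceeded it was not tested. A change of fibre type in adjoining muscle and an effect of compression on the disc's own cells stay open and were not tested.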
